A study of Apostichopus japonicus with 3 samples.

How the data were processed

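Messenger RNA was measured by sequencing in intestines of the sea cucumber Apostichopus japonicus, an echinoderm that spends the warm season in aestivation, a dormant state in which it stops feeding. The series has 3 libraries, 1 per stage: non-aestivation, deep aestivation and arousal from aestivation. Per the series' design text, at least 15 individuals were used per stage, and whether their RNA was pooled before library preparation is not given in the sources used here. Per the labels' protocols, total RNA was treated with DNase, mRNA was enriched with oligo(dT) beads and broken into pieces of about 200 bp, cDNA was primed with random hexamers, and the libraries were amplified by PCR. The submitters' processing notes name CASAVA 1.5. The aligner, the assembler and the read length are not given in the sources used here.

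Each deposited table lists isotigs, the assembled transcript sequences of a transcriptome without a reference genome. Per the file headers, it gives for each isotig a whole-number count of uniquely aligned reads, the isotig's length, the percent of that length covered by reads, an RPKM value (reads scaled by the length of the isotig and by the total of aligned reads), gene ontology terms and the best match in a protein database. The deposited read counts sum in each library to the total that the header names, 1022383 in non-aestivation, 892745 in deep aestivation and 944773 in arousal. Recomputing the authors' RPKM from reads, length and that total gave the deposited RPKM values with relative differences of at most 4.96e-15. Isotigs with 0 reads in a library are left out of its table and were taken as 0. Groups follow the labels of the samples. The table recorded for the sample labelled non-aestivation carries the file name code of arousal, and the table recorded for the sample labelled arousal carries the code of non-aestivation. Nothing inside the tables names a stage, so every direction between these 2 libraries, and every statement on which of them was compared with deep aestivation, rests on the labels. The reference table of gene names shares 0 identifiers with the isotigs, so gene names come from the best protein matches and no genome coordinates were used.

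With 1 library per stage there is no spread between replicates, no test was made and no p-value is given. The measure was the log2 ratio of RPKM + 0.5, over the 18352 of 20712 isotigs with a mean RPKM of at least 1 across the 3 libraries. The pseudocount shrinks ratios of isotigs with few reads in both libraries. Where 1 library had 0 reads, 0.5 RPKM lies below the value of a single read in a 1 kb isotig. The ratio can then exceed the bound defined below. For isotig27803, with 0 reads in non-aestivation and 61 in deep aestivation, the log2 ratio was 8.46 and the bound 23.3-fold. Such isotigs can rank ahead of isotigs with larger measured folds, and they can move list medians away from 0. Folds of single isotigs are ratios of the shares of all reads with an exact 95% conditional binomial (Clopper-Pearson) interval. An isotig was called higher or lower beyond counting error when it was at least 2-fold apart on the log2 scale and its 99.9% interval excluded equal expression, which compares 2 libraries and not the conditions. A fold against 0 reads is given as a bound, computed with a floor of 3 reads in that library. The words at least refer to this floor alone. The bound takes the reads of the other library as exact, and the lower end of the 95% interval lies below it. For isotig15359 in deep aestivation over non-aestivation the bound was 209-fold and that end 169-fold. PCR reads without molecular identifiers are not independent molecules, so intervals, floors and calls cover counting error only. To show what counting alone gives, both libraries of a comparison were drawn 100 times from equal expression, and the mean number of isotigs passing each criterion was recorded.

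The 24 gene lists were matched on the text of the best protein match. The rule for named isotigs, the list topics, the thresholds and most alternative settings were fixed before the data were examined. The text patterns of the lists were corrected once, by reading the matched descriptions before any ratio of a list was computed: a pattern for the sperm protein bindin had taken in every description with the word binding, and other mismatched descriptions were excluded. The rule named, per comparison, the 5 isotigs with the highest and the 5 with the lowest log2 ratio among those with a named match, a mean RPKM of at least 5 and at least 50 reads over the libraries compared, and the highest and the lowest member of each list. For deep aestivation apart from both other stages it named the 5 isotigs with the largest smaller ratio in each direction. Isotigs that the rule names in no comparison are named with a statement that they were chosen after their values were seen. A further 14 protein families were summed over their isotigs, also chosen after the values were seen, and the patterns of 4 of them were then corrected by reading the matched descriptions. A list is described by its median log2 ratio, a 95% binomial interval of the median, and the percentile of that median among 10000 random lists of the same size drawn from isotigs with a protein match in 10 bins of mean RPKM. Percentiles are given for the 21 lists with at least 5 members. Medians of random lists need not centre on 0, so a percentile places a list against other isotigs with a protein match and not against 0. In deep aestivation over non-aestivation, for example, the chromatin list had a median of 0.29 at percentile 55.8. Reads were aligned uniquely, so isotigs of near-identical genes or alleles can gain or lose reads together, and values of single isotigs within a family are uncertain for that reason.

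The method was tested on simulated data drawn from the real isotigs and library totals, with 100 isotigs changed 4-fold and 100 changed 8-fold. The changed isotigs were taken from those with a mean RPKM of at least 5. Recovery among the lower isotigs of the set analysed was therefore not tested. Of those changed 4-fold, 54% were called in deep aestivation over non-aestivation, 54% in arousal over deep aestivation and 56% in arousal over non-aestivation. Of those changed 8-fold, 79%, 81% and 79% were called. Among the isotigs with at least 50 reads over both libraries, the 4-fold changes were called in 97.4%, 97.5% and 95.6%, and the 8-fold changes in 100%. Of the unchanged isotigs among the 20712, 9, 9 and 5 were called. A single read in a 1 kb isotig equals 0.978, 1.12 and 1.06 RPKM in the non-aestivation, deep aestivation and arousal libraries.

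The alternative settings were pseudocounts of 0.1 and 1, no filter, a mean RPKM of at least 5, a 4-fold threshold, calls beyond counting error, 3 other scalings of the libraries (median ratio, upper quartile, and totals without the 50 isotigs of highest mean RPKM), and an exchange of the libraries of the outer stages. Counting only isotigs with a protein match, summing RPKM over isotigs with the same best match, and the list patterns as first written were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.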

Results

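Transcripts of the intestine were counted in 3 libraries of the sea cucumber Apostichopus japonicus, 1 each for non-aestivation, deep aestivation and arousal from aestivation. Aestivation is the summer dormancy of this species, in which feeding stops and the gut shrinks. The libraries held 1.02 M, 0.893 M and 0.945 M uniquely aligned reads, in that order, and listed 18327, 18385 and 17651 isotigs. Of these, 8741, 8755 and 8286 had at least 10 reads, and the median isotig listed had 9, 9 and 8 reads and was covered over 33.4%, 34.4% and 33.4% of its length. Of 20712 isotigs in any library, 15392 were found in all 3, and 10174 had a protein match. The stages were not replicated, so differences are given by size and counting error alone.

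A few transcripts took a large part of the reads. The 20 most abundant isotigs held 28.1% of the reads in the non-aestivation library, 32.2% in the deep aestivation library and 35.6% in the arousal library. Much of this was held by 3 isotigs without a protein match, with 17.5%, 15.1% and 13.3% of the reads in that order. The largest with a protein match over the 3 libraries together were named after their values were seen. They were major yolk protein 1 (isotig13120), an iron-binding transferrin-like protein stored in echinoderm gonads and made in the gut, and intestinal fatty acid binding protein 2 (isotig19264), a carrier of fatty acids inside gut cells. Major yolk protein 1 held 2.45% of reads in non-aestivation (exact 95% binomial interval 2.42 to 2.48), 10.2% in deep aestivation (10.1 to 10.2) and 10.7% in arousal (10.6 to 10.8). The fatty acid binding protein held 1.62% (1.60 to 1.65), 0.319% (0.308 to 0.331) and 5.44% (5.39 to 5.48). In deep aestivation its 2849 reads were fewer than the 13091 of apolipoprotein B (isotig13070), also named after its values were seen. Pearson's r of log2(RPKM + 0.5) across isotigs, which are not independent replicates, was 0.73 between deep aestivation and non-aestivation, 0.74 between arousal and deep aestivation and 0.75 between arousal and non-aestivation.

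The file names of the non-aestivation and arousal libraries are crossed against their labels. Values below follow the labels. If the names were right, each comparison of deep aestivation with one of these stages would be the comparison with the other, and each direction between arousal and non-aestivation would turn around. Statements that deep aestivation was higher or lower than both other libraries hold either way.

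**Figure D1:**
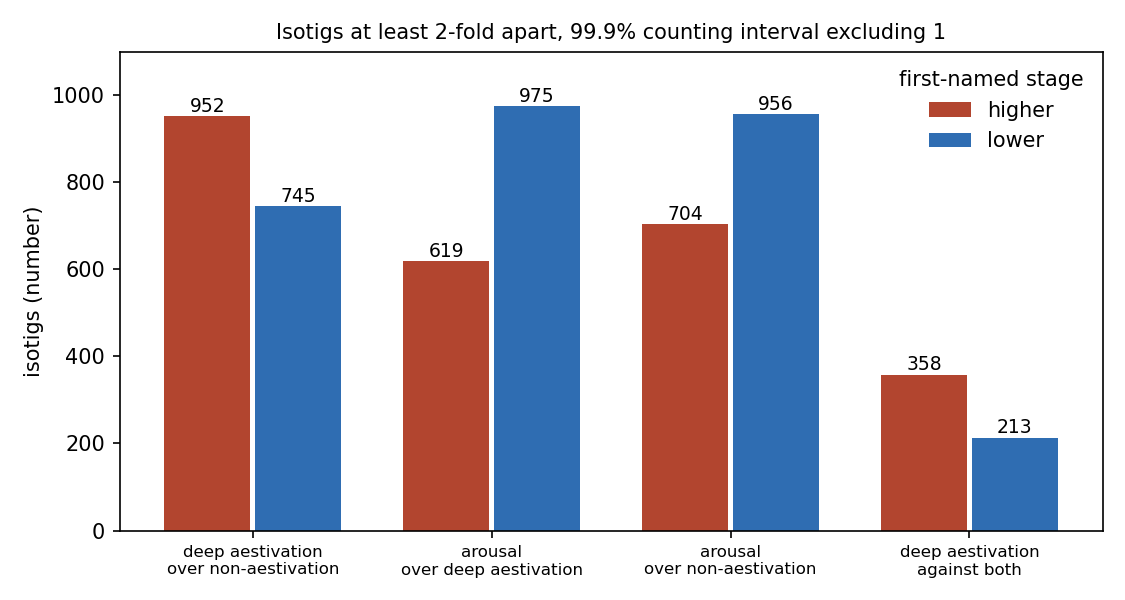
Number of isotigs at least 2-fold apart beyond counting error in each comparison, with bars for isotigs higher and lower in the first-named stage. The counts run from 213 isotigs lower in deep aestivation than in both other libraries to 975 lower in arousal than in deep aestivation.

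Deep aestivation is compared first with non-aestivation, 1 library against 1. Lists of protein synthesis and of mitochondrial energy metabolism were lower by their medians in the deep aestivation library, with most members neither higher nor lower, while several digestive enzymes were far higher. Of 63 cytosolic ribosomal proteins, 24 were lower beyond counting error, 0 were higher and 39 were neither, with a median log2 ratio of -0.96 (95% interval -1.0 to -0.81). Of 62 components of oxidative phosphorylation, 12 were lower, 0 were higher and 50 were neither (median -0.85, -1.04 to -0.65). Digestive enzymes went both ways, with 14 of 48 higher, 4 lower and 30 neither (median 0.70, -0.20 to 1.32). This median became 0.57 with members at 0 reads set to their bound.

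Among digestive enzymes, 2 isotigs of trypsin-like serine protease, which cuts dietary protein, stood highest. Isotig26752 had 1 read in non-aestivation and 405 in deep aestivation (464-fold, 82.8 to 1.84e+04), and isotig21645 had 6 and 1169 reads (223-fold, 102 to 609). A further isotig with the same best match, isotig13602, went the other way, with 1220 and 7 reads (152-fold lower, 73.6 to 379). An isotig matching Rp2 lipase (isotig27803) had 0 and 61 reads and was at least 23.3-fold higher. Isotigs matching proprotein convertase subtilisin/kexin type 9, a secreted protein that in vertebrates controls the number of low-density lipoprotein receptors, were also among the highest: isotig15359 had 0 and 547 reads (at least 209-fold higher) and isotig07647 had 0 and 92 (at least 35.1-fold higher). The lowest isotigs were a beta-tubulin (isotig18713, 288 and 0 reads, at least 83.8-fold lower), isotig13602, a match to titin (isotig01194, 61 and 0 reads, at least 17.8-fold lower), a ribosomal L10e/P0 isotig (isotig10296, 121 and 1 reads, 106-fold lower, 18.6 to 4.21e+03) and a match to the actin-binding MICAL-3 (isotig01569, 68 and 0 reads, at least 19.8-fold lower). Another L10e/P0 isotig, named after its values were seen, had 620 and 284 reads (isotig10295).

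The lists of energy metabolism lay low in deep aestivation. In the citrate cycle 5 of 23 members were lower, 0 higher and 18 neither (median -0.78, -1.54 to -0.12, percentile 0.09 among random lists). The lowest was succinyl-CoA synthetase alpha (isotig06621, 62 and 12 reads, 4.51-fold lower, 2.41 to 9.20). In oxidative phosphorylation (percentile 0) the lowest was cytochrome c oxidase subunit VB (isotig07853, 43 and 7 reads, 5.36-fold lower, 2.39 to 14.1). Glycolysis had 1 of 11 members lower, a gamma-enolase isotig (isotig06325, 32 and 8 reads, named by the rule in arousal over non-aestivation), and 10 neither (median -0.75, -1.74 to 0.71, percentile 1.86), and another gamma-enolase isotig had 150 and 75 reads (isotig06324, 1.75-fold lower, 1.32 to 2.34). Fatty acid oxidation had 10 of 10 members neither higher nor lower, with a median of -0.89 (-1.58 to 0.31, percentile 0.52).

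Ribosomal proteins (percentile 0) ranged from L44 (isotig03880, 197 and 24 reads, 7.17-fold lower, 4.68 to 11.5) to S27 (isotig08100, 280 and 296 reads, 1.21-fold, 1.02 to 1.43). Their share of all reads was 8.05% in non-aestivation and 4.14% in deep aestivation. Of 27 translation factors, 5 were lower, 0 higher and 22 neither (median -0.76, -1.18 to -0.28, percentile 0.01). Of 29 genes of DNA replication and the cell cycle, 6 were lower, 0 higher and 23 neither (median -0.49, -1.44 to 0.01, percentile 0.03). Proliferating cell nuclear antigen, the sliding clamp of DNA polymerase, was 3.84-fold lower (isotig08755, 66 and 15 reads, 2.17 to 7.25). Antioxidant and detoxification genes had 14 of 73 members lower, 3 higher and 56 neither (median -0.24, -0.62 to 0.39, percentile 0.06, and -0.14 with members at 0 reads set to their bound). Glutathione S-transferase omega 1 was 5.37-fold lower (isotig21949, 160 and 26 reads, 3.54 to 8.48), and a cytochrome P450 of family 3 was 3.28-fold higher (isotig14796, 96 and 275 reads, 2.59 to 4.18).

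Heat shock proteins and chaperones were mostly neither higher nor lower (41 of 44), with 2 higher and 1 lower. Their median was -0.26 (-0.64 to 0.15, percentile 0.62), with an interval that spans 0. DnaJ homolog B6 was 4.42-fold higher (isotig17584, 14 and 54 reads, 2.42 to 8.61) and Dnajb11 3.17-fold lower (isotig15164, 116 and 32 reads, 2.12 to 4.84). Innate immune genes had 13 of 128 members higher, 9 lower and 106 neither (median 0.25, or 0.16 with members at 0 reads set to their bound), from lysozyme, which breaks bacterial cell walls, 37.2-fold higher (isotig18269, 2 and 65 reads, 9.90 to 314), to a fibrinogen-like protein 9.76-fold lower (isotig21446, 123 and 11 reads, 5.27 to 20.1). Among genes of ubiquitin, proteasome and autophagy 7 of 104 were higher and 5 lower, with ubiquitin-conjugating enzyme E2 H 8.67-fold higher (isotig16108, 7 and 53 reads, 3.93 to 22.6) and cathepsin L2 2.5-fold lower (isotig13709, 1106 and 387 reads, 2.22 to 2.81). Of 61 extracellular matrix genes, 2 were higher, 6 lower and 53 neither (median 0.30, 0.00 to 0.59, percentile 64.5). A match to ADAM metallopeptidase with thrombospondin motif 9 was 3.74-fold higher (isotig07258, 26 and 85 reads, 2.39 to 6.05). A fibrillar collagen was 4.64-fold lower (isotig14440, 154 and 29 reads, 3.10 to 7.15). Apoptosis (22 of 22), chromatin (28 of 29), insulin, TOR and AMPK signalling (10 of 10) and the circadian clock (6 of 6) had nearly all or all members neither higher nor lower.

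Among the marker lists of other cell types, 4 of 25 gonad and yolk genes were higher in deep aestivation and 0 lower. Their share of reads was 2.56% in non-aestivation and 10.5% in deep aestivation, nearly all of it major yolk protein 1. That protein is also made in the gut, as stated above, so this share does not mark gonad tissue. A vitellogenin match was 5.01-fold higher (isotig17734, 105 and 459 reads, 4.04 to 6.25). Neuronal and synaptic genes had 6 of 41 members higher and 2 lower (median 0.72, 0.08 to 1.10, percentile 96.5), from an acetylcholinesterase-like isotig 7.79-fold higher (isotig23247, 10 and 68 reads, 3.99 to 17.0) to an acetylcholine receptor subunit 31.4-fold lower (isotig05318, 72 and 2 reads, 8.39 to 265). Muscle genes had 2 of 31 higher and 4 lower, with a median of 0.41 that became 0.00 when members with 0 reads were set to their bound. The lists of gluconeogenesis (3 members, median -0.33), iron binding (3, 0.41) and coelomocytes (2) were too small for a percentile. Coelomocytes had no clear direction, since their median of -1.57 became 0.23 with the member at 0 reads set to its bound.

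Altogether 952 isotigs were higher and 745 lower in deep aestivation than in non-aestivation beyond counting error, where equal expression gave 2.92 and 2.33. At 2-fold alone the counts were 4502 and 3247, against 1781 and 1888 from equal expression. The split depended on scaling: with median-ratio scaling 721 were higher and 954 lower, and with upper-quartile scaling 756 and 914. These scalings shifted the median log2 ratio of all isotigs, 0.16 here, by -0.12 and -0.11.

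**Figure D2:**
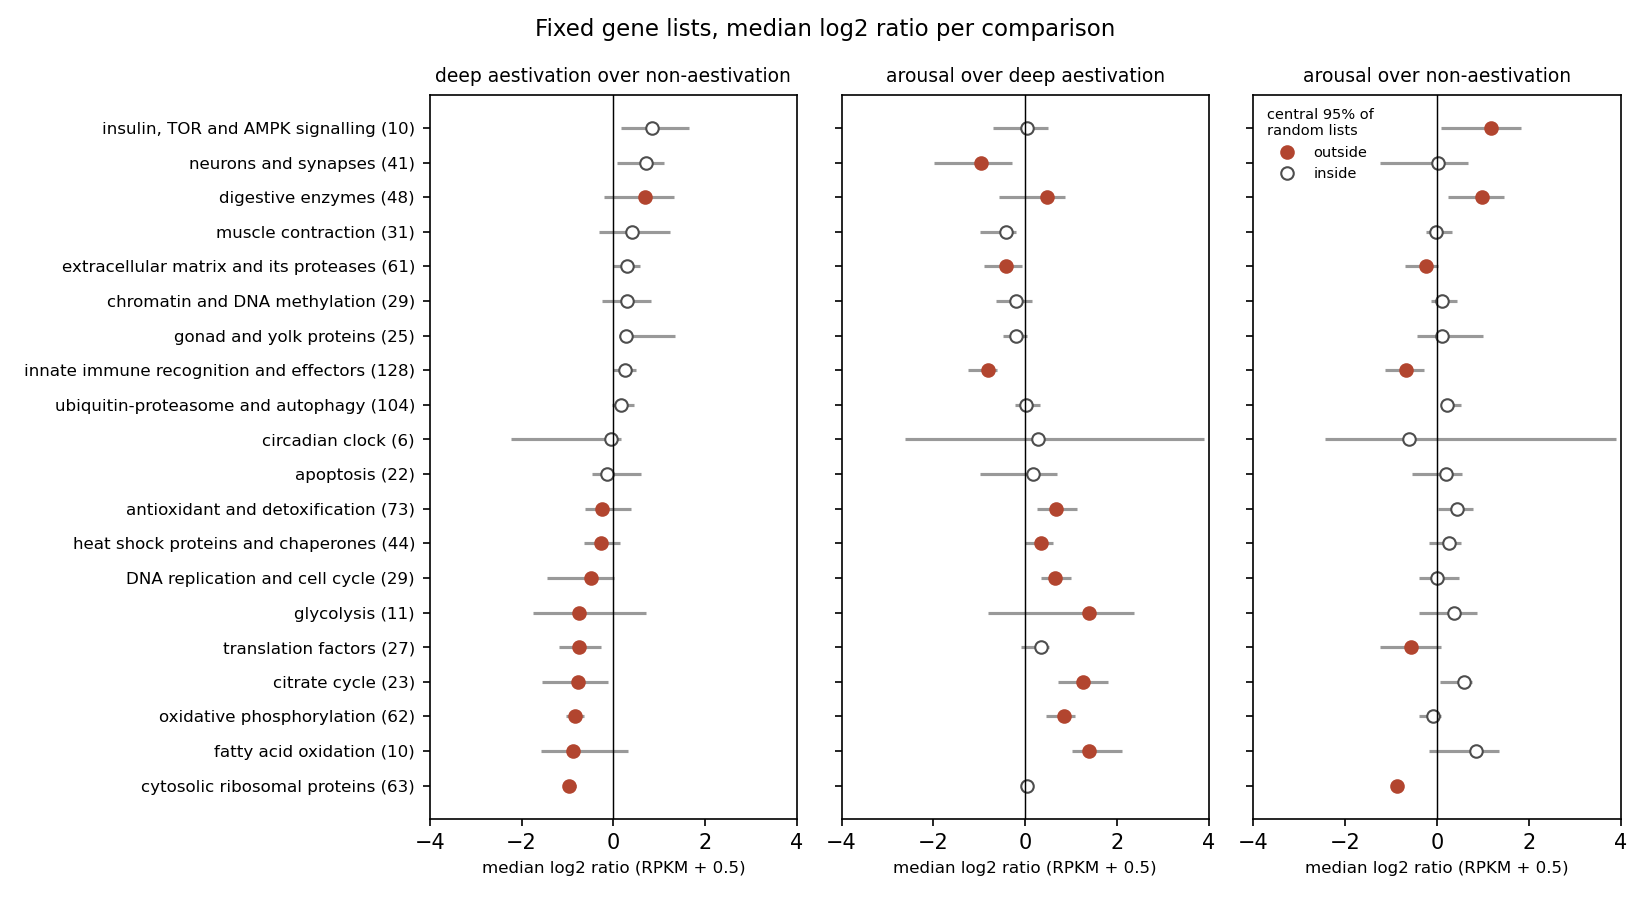
Median log2 ratio of RPKM + 0.5 for 20 gene lists in each comparison, with the number of members in parentheses, lines for the 95% binomial interval of the median, and filled points for medians outside the central 95% of random lists. Ribosomal proteins lie at -0.96 in deep aestivation over non-aestivation and at 0.04 in arousal over deep aestivation, and the citrate cycle lies at -0.78 and 1.25.

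The library labelled arousal is compared next with that of deep aestivation. Lists of energy metabolism were higher by their medians in the arousal library, ribosomal proteins stood near the level of deep aestivation in the scaling reported, innate immune genes were lower by their median, and neuronal genes went both ways. In the citrate cycle 9 of 23 members were higher, 0 lower and 14 neither (median 1.25, 0.71 to 1.80), and in oxidative phosphorylation 10 of 62 were higher, 0 lower and 52 neither (median 0.85, 0.44 to 1.08). Ribosomal proteins had 1 of 63 members higher, 1 lower and 61 neither (median 0.04, -0.04 to 0.15). This median was 0.24 with median-ratio scaling and 0.23 with upper-quartile scaling. Innate immune genes had 25 of 128 members lower, 5 higher and 98 neither (median -0.82, -1.24 to -0.61). This median became -0.49 with members at 0 reads set to their bound.

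The highest isotigs in arousal were the L10e/P0 isotig (isotig10296, 1 read in deep aestivation and 100 in arousal, 94.5-fold, 16.6 to 3.77e+03), a lactose-binding lectin (isotig11607, 2 and 136 reads, 64.3-fold, 17.4 to 536), a match to GTPase IMAP 7 (isotig16046, 1 and 59 reads, 55.8-fold, 9.62 to 2.24e+03), methylenetetrahydrofolate reductase, which makes the folate form used to methylate homocysteine (isotig13139, 24 and 918 reads, 36.1-fold, 24.1 to 56.7), and a porin (isotig22637, 35 and 1131 reads, 30.5-fold, 21.8 to 44.1). The lowest were the Rp2 lipase (isotig27803, 61 and 0 reads, at least 21.5-fold lower), serum amyloid A, an acute phase protein (isotig08093, 69 and 0 reads, at least 24.3-fold lower), lysozyme (isotig18269, 65 and 0 reads, at least 22.9-fold lower), a subtilisin/kexin type 9 match (isotig07647, 92 and 0 reads, at least 32.5-fold lower) and a trypsin-like protease (isotig26752, 405 and 4 reads, 107-fold lower, 41.5 to 395).

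Within the energy lists, cytosolic malate dehydrogenase was 4.48-fold higher in arousal (isotig18460, 89 and 422 reads, 3.56 to 5.70), and an iron-sulfur subunit of NADH dehydrogenase 3.95-fold higher (isotig09425, 17 and 71 reads, 2.30 to 7.15). Glycolysis had 2 of 11 members higher and 0 lower (median 1.39, -0.82 to 2.36, above the central 95% of random lists). The interval spans 0, and the median became 0.96 with members at 0 reads set to their bound. Hexokinase, the entry enzyme of glycolysis, was among the higher members (isotig13226, 113 and 333 reads, 2.78-fold, 2.24 to 3.48). Fatty acid oxidation had 3 of 10 higher and 0 lower (median 1.38, 1.01 to 2.11), with acyl-CoA oxidase 2.5-fold higher (isotig14761, 91 and 241 reads, 1.96 to 3.22). Of 5 genes of fatty acid and sterol synthesis, fatty acid synthase was 5.07-fold higher (isotig17168, 33 and 177 reads, 3.48 to 7.59) and a very long chain elongase 2.70-fold lower (isotig15664, 115 and 45 reads, 1.90 to 3.91). Digestive enzymes again went both ways, with 10 of 48 higher and 9 lower (median 0.47, -0.57 to 0.86), from a cytosolic beta-glucosidase 20.7-fold higher (isotig16411, 25 and 548 reads, 13.9 to 32.3) to the trypsin-like isotig26752.

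Antioxidant and detoxification genes had 16 of 73 members higher, 3 lower and 54 neither (median 0.66, 0.26 to 1.13, percentile 100). Catalase, which breaks down hydrogen peroxide, was 7.30-fold higher (isotig06119, 11 and 85 reads, 3.88 to 15.2), while a copper/zinc superoxide dismutase was 5.73-fold lower (isotig17129, 157 and 29 reads, 3.84 to 8.83). DNA replication and the cell cycle had 3 of 29 higher and 0 lower (median above the central 95% of random lists), with proliferating cell nuclear antigen 3.21-fold higher (isotig08755, 15 and 51 reads, 1.78 to 6.15). Heat shock proteins had 2 of 44 higher and 0 lower (percentile 98.9), and Dnajb11 was 3.13-fold higher (isotig15164, 32 and 106 reads, 2.09 to 4.81). Translation factors had 1 of 27 higher and 0 lower (percentile 96.9).

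Extracellular matrix genes had 10 of 61 members lower and 2 higher (median -0.42, -0.91 to -0.07, percentile 1.33), with laminin alpha, a basement membrane protein, 6.61-fold lower (isotig15850, 150 and 24 reads, 4.28 to 10.6). Neuronal and synaptic genes had 11 of 41 lower, 6 higher and 24 neither (median -0.97, -1.98 to -0.30, percentile 0, and -0.59 with members at 0 reads set to their bound). An acetylcholinesterase was 9.39-fold lower (isotig14738, 71 and 8 reads, 4.52 to 22.6). Muscle genes had 3 of 31 higher, 1 lower and 27 neither, with a median of -0.43 (-0.99 to -0.21, percentile 8.19), and gonad and yolk genes 0 of 25 higher and 1 lower. Genes of ubiquitin, proteasome and autophagy had 5 of 104 higher and 0 lower, with cathepsin L2, a lysosomal protease, 5.55-fold higher (isotig13709, 387 and 2272 reads, 4.98 to 6.19). Apoptosis had 2 of 22 lower, chromatin 1 of 29 lower, and insulin, TOR and AMPK signalling and the circadian clock had 0 higher or lower. Medians of the smallest lists were 1.11 in gluconeogenesis, -0.27 in iron binding and -0.51 in coelomocytes.

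In this comparison 619 isotigs were higher and 975 lower in arousal beyond counting error, against 2.24 and 2.56 under equal expression, and at 2-fold alone 2808 and 4706, against 1885 and 1771. The split turned with scaling, to 839 higher and 732 lower with median-ratio scaling and 824 and 737 with upper-quartile scaling. Both shifted the median log2 ratio of all isotigs, -0.16 here, by 0.16.

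**Figure D3:**
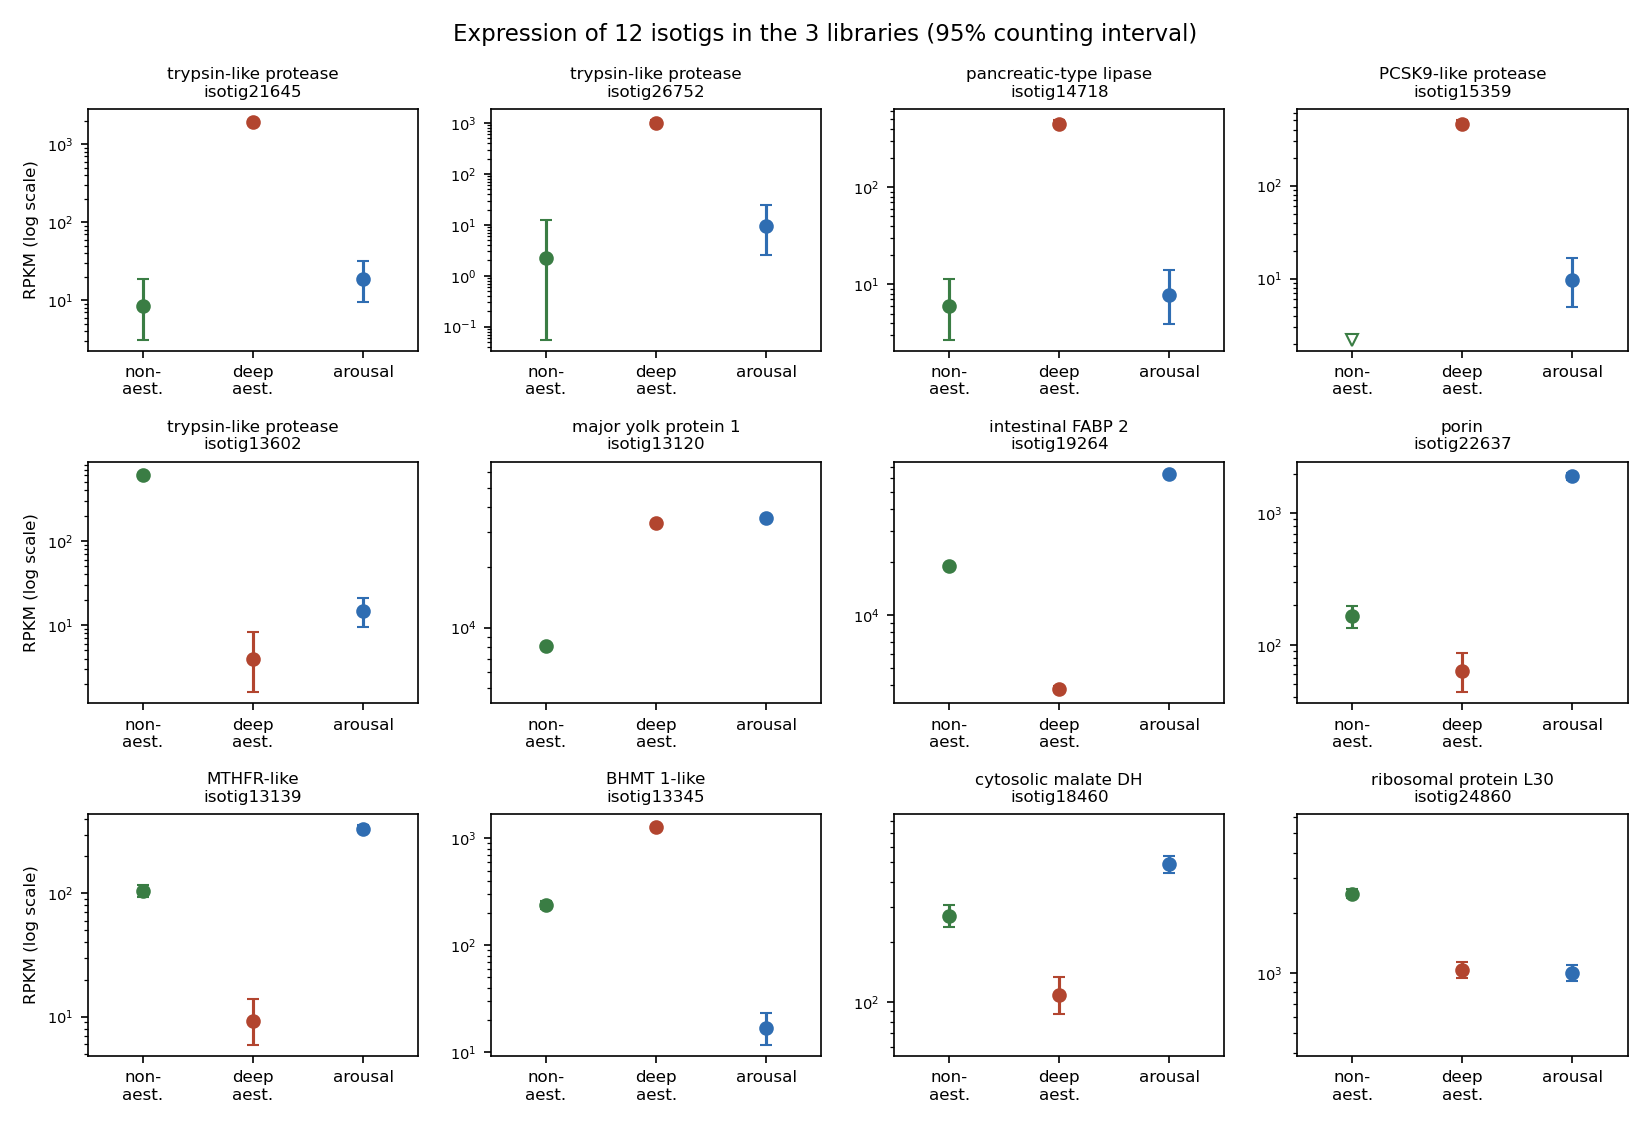
RPKM of 12 isotigs, chosen after their values were seen, in the 3 libraries on log scales that differ between panels, with exact 95% counting intervals as bars and an open triangle at the value of 3 reads where there were 0. Trypsin-like isotig21645 had 6, 1169 and 12 reads in non-aestivation, deep aestivation and arousal, and the fatty acid binding protein (isotig19264) had 16574, 2849 and 51380.

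In the comparison of arousal with non-aestivation, all directions rest on the labels that the file names contradict. In the library labelled arousal, ribosomal proteins and translation factors were lower and digestive enzymes were higher by their medians. Of 63 ribosomal proteins, 13 were lower, 0 higher and 50 neither (median -0.87, -0.96 to -0.80, percentile 0), with L30 2.49-fold lower (isotig24860, 1344 and 499 reads, 2.24 to 2.76). Of 48 digestive enzymes, 14 were higher, 2 lower and 32 neither (median 0.99, 0.23 to 1.46, percentile 100). That median became 0.70 with members at 0 reads set to their bound. These enzymes ranged from maltase-glucoamylase, which releases glucose from starch, 5.69-fold higher (isotig19900, 46 and 242 reads, 4.14 to 7.98) to a trypsin-like protease 41.8-fold lower (isotig13602, 1220 and 27 reads, 28.6 to 63.6).

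The highest isotigs in the library labelled arousal were a cellular retinol-binding protein, a carrier of vitamin A (isotig11232, 0 reads in non-aestivation and 150 in arousal, at least 54.1-fold higher), GTPase IMAP 7 (isotig16046, 0 and 59 reads, at least 21.3-fold higher), angiotensin-converting enzyme, a peptidase (isotig07117, 0 and 52 reads, at least 18.8-fold higher), a growth factor receptor (isotig06516, 4 and 216 reads, 58.4-fold, 22.5 to 216) and a secreted lectin (isotig11608, 1 and 49 reads, 53.0-fold, 9.08 to 2.14e+03). Summed over its 6 isotigs, cellular retinol-binding protein went the other way, with 938 and 597 reads (1.45-fold lower, 1.31 to 1.61). This sum was chosen after its values were seen. Beyond counting error 1 of these isotigs was higher and 1 lower. The lowest were the beta-tubulin (isotig18713, 288 and 0 reads, at least 88.7-fold lower), a matriptase-like protease (isotig25725, 134 and 0 reads, at least 41.3-fold lower), a low-density lipoprotein receptor-related protein (isotig21129, 138 and 0 reads, at least 42.5-fold lower), a CUB and sushi domain protein (isotig11651, 306 and 1 reads, 283-fold lower, 50.4 to 1.12e+04) and a match to the glutamate receptor GluR2/B (isotig13309, 1245 and 5 reads, 230-fold lower, 98.3 to 710).

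Translation factors had 5 of 27 members lower and 0 higher (median -0.57, -1.24 to 0.09, percentile 0.32). Fatty acid and sterol synthesis had 1 of 5 members higher, 0 lower and 4 neither, with a median of 2.82 that became 1.66 with members at 0 reads set to their bound. The higher member, fatty acid synthase, was 7.98-fold higher (isotig17168, 24 and 177 reads, 5.19 to 12.8). Fatty acid oxidation had 2 of 10 higher (median 0.84), with acyl-CoA oxidase 3.10-fold higher (isotig14761, 84 and 241 reads, 2.41 to 4.03). The citrate cycle had 0 of 23 higher or lower (median 0.59, 0.06 to 0.77), glycolysis 0 of 11, and oxidative phosphorylation 1 of 62 higher and 4 lower (median -0.10, or -0.010 with members at 0 reads set to their bound, percentile 3.84), with ATP synthase gamma 4.01-fold lower (isotig08836, 139 and 32 reads, 2.72 to 6.09). Insulin, TOR and AMPK signalling had 1 of 10 higher (median 1.17, 0.09 to 1.82, percentile 99.1), p70 ribosomal protein S6 kinase, which acts downstream of TOR (isotig13410, 28 and 65 reads, 2.51-fold, 1.59 to 4.06).

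Innate immune genes had 14 of 128 members lower, 8 higher and 106 neither (median -0.69, -1.14 to -0.29, percentile 0). The median became -0.24 with members at 0 reads set to their bound. Extracellular matrix genes had 11 of 61 lower and 4 higher (median -0.24, -0.70 to 0.01, percentile 0.46), with a tenascin-R match 28.2-fold lower (isotig09541, 61 and 2 reads, 7.48 to 238). Antioxidant and detoxification genes had 10 of 73 higher, 6 lower and 57 neither (median 0.43, 0.02 to 0.78, percentile 92.1). Against that median, superoxide dismutase (isotig17129) was 4.72-fold lower (148 and 29 reads, 3.15 to 7.29). Gonad and yolk genes had 5 of 25 higher and 1 lower, and the vitellogenin match was 8.42-fold higher (isotig17734, 105 and 817 reads, 6.86 to 10.4). Neuronal genes had 4 of 41 higher and 3 lower, muscle genes 1 of 31 higher and 3 lower, heat shock proteins 3 of 44 higher and 0 lower, ubiquitin, proteasome and autophagy 7 of 104 higher and 1 lower, DNA replication 1 of 29 higher, apoptosis 1 of 22 higher and 1 lower, chromatin 1 of 29 lower, and the circadian clock 0 of 6. A titin-like isotig was 4.12-fold lower (isotig13411, 799 and 179 reads, 3.50 to 4.88). Gluconeogenesis, iron binding and coelomocytes had medians of 0.31, -0.18 and -2.08. The last became -0.32 with the member at 0 reads set to its bound.

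In all, 704 isotigs were higher and 956 lower in the library labelled arousal beyond counting error, against 2.52 and 2.69 under equal expression, and at 2-fold alone 3429 and 4201, against 1696 and 1806. The split turned to 531 higher and 283 lower among isotigs with a protein match and to 473 and 230 in sums by best match, both counted after the data were seen. It was 797 and 838 without the 50 most abundant isotigs in the totals. Over the 63 pairs of list and comparison with a percentile, 29 medians lay outside the central 95% of random lists. The comparisons share libraries and members of a list vary together, so no chance level is set against this count. With members at 0 reads set to their bound, no median of these 63 pairs took the opposite sign.

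Isotigs that set deep aestivation apart from both other libraries do not depend on which outer library is which. Digestive enzymes and subtilisin/kexin type 9 matches were among those higher, and mitochondrial, antioxidant and cell cycle genes among those lower. Of 48 digestive enzymes, 9 were higher than in both other libraries and 3 lower. Besides both trypsin-like isotigs, the 9 included pancreatic-type triacylglycerol lipase, which splits dietary fat (isotig14718, 9, 594 and 11 reads in non-aestivation, deep aestivation and arousal), alpha-amylase, which splits starch (isotig16864, 0, 71 and 4 reads), and a zinc carboxypeptidase (isotig14682, 4, 66 and 0 reads). The 3 lower ones were a membrane alanine aminopeptidase (isotig15581, 324, 93 and 581 reads) and 2 cytosolic beta-glucosidases (isotig16411, 156, 25 and 548 reads, and isotig20949, 60, 14 and 286 reads). Apart from the trypsin-like isotigs and isotig16411, these members were named after their values were seen.

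By the rule for named isotigs, the highest were the Rp2 lipase (isotig27803, 0, 61 and 0 reads), subtilisin/kexin type 9 matches (isotig07647, 0, 92 and 0 reads, and isotig07646, 0, 60 and 0 reads, at least 22.9-fold and 21.2-fold higher than non-aestivation and arousal) and the trypsin-like isotig26752 and isotig21645. The lowest were L10e/P0 (isotig10296, 121, 1 and 100 reads), cellular retinol-binding protein (isotig24421, 109, 3 and 93 reads, 31.7-fold below non-aestivation, 10.6 to 156, and 29.3-fold below arousal, 9.72 to 145), a microneme protein 4 match (isotig25359, 40, 1 and 32 reads), titin (isotig01194, 61, 0 and 15 reads) and the lactose-binding lectin (isotig11607, 33, 2 and 136 reads).

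In the citrate cycle list 5 of 23 members were lower in deep aestivation than in both. They were succinyl-CoA synthetase alpha (isotig06621, 62, 12 and 39 reads), pyruvate dehydrogenase beta (isotig07276, 37, 6 and 38 reads), citrate synthase (isotig15148, 142, 57 and 212 reads) and 2 malate dehydrogenase isotigs (isotig16250, 285, 85 and 290 reads, and isotig18460, 253, 89 and 422 reads). Of these, isotig07276, isotig15148 and isotig16250 were named after their values were seen. Isotig18460 matches the cytosolic form, so this list, matched on text, is not confined to enzymes of the cycle itself. Oxidative phosphorylation had 5 of 62 members lower than in both, antioxidant genes 8 of 73, and DNA replication and the cell cycle 3 of 29, with 0 higher in each of these lists. Innate immune genes had 8 of 128 higher and 1 lower. The 8 included a C-type lectin, named after its values were seen (isotig15031, 836, 2076 and 631 reads). Neuronal genes had 4 of 41 higher and 1 lower.

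Deep aestivation stood above both other libraries in 358 isotigs and below both in 213 beyond counting error, where equal expression in 3 libraries gave 0.04 and 0.17 and independent lists of the same sizes gave 50.6 and 25.1. Both ratios share the deep aestivation library, so part of the excess may come from that library, and 1 library cannot be split. At 2-fold alone the counts were 1990 and 1564, against 566 and 1094 from equal expression and 1154 and 497 from independent lists. With median-ratio scaling the counts beyond counting error were 272 and 294, and with upper-quartile scaling 277 and 285.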

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

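The counts over isotigs with a protein match, the counts summed by best match and the list patterns as first written were chosen only after the data were seen. No paired analysis was possible because each stage has 1 library, and for the same reason no library could be left out. Depth is a limit: the median isotig listed had 8 or 9 reads, and most 2-fold differences were not called beyond counting error. Equal expression nevertheless gave fewer 2-fold differences than were counted, in each comparison and direction. Counts are given below as higher and lower in deep aestivation over non-aestivation, in arousal over deep aestivation, in arousal over non-aestivation, and in deep aestivation against both. A 4-fold threshold gave 1725 and 1328, 1168 and 2150, 1356 and 1886, and 534 and 668. Calls beyond counting error gave 952 and 745, 619 and 975, 704 and 956, and 358 and 213. A mean RPKM of at least 5 gave 2951 and 2082, 1833 and 3066, 2341 and 2684, and 1202 and 960. Isotigs with a protein match gave 2493 and 1334, 1464 and 1986, 2039 and 1420, and 997 and 720. Sums by best match gave 1980 and 987, 1103 and 1524, 1624 and 1040, and 759 and 506. These settings count fewer isotigs by construction. Under both other pseudocounts, no filter, the 3 other scalings and the exchange of the outer stages, all counts stayed within 1.5 times those reported.

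Of the list medians recomputed, 517 stayed within their 95% interval or did not move, 40 moved and 10 turned around. Turned counts only medians outside the central 95% of random lists: the exchange of the outer stages changed the sign of 29 of 63 medians, and the other settings that of 10 of 504. Fatty acid and sterol synthesis, with 5 members, has no interval, so any change counts as moved. Its medians, in deep aestivation over non-aestivation, arousal over deep aestivation and arousal over non-aestivation, were 0.65, 1.82 and 2.99 with a pseudocount of 0.1, 0.63, 1.28 and 2.01 with 1, 1.39, 1.17 and 2.97 at a mean RPKM of at least 5, 0.50, 1.67 and 2.86 with median-ratio scaling, 0.52, 1.68 and 2.89 with upper-quartile scaling, and 0.63, 1.60 and 2.86 without the 50 most abundant isotigs. The ribosomal median was -1.11 in deep aestivation over non-aestivation and 0.24 in arousal over deep aestivation with median-ratio scaling, -1.09 and 0.23 with upper-quartile scaling, and -0.80 in arousal over non-aestivation without the 50 most abundant isotigs. All 10 turned medians came from exchanging the outer stages, which by construction negates each ratio between them. In deep aestivation over non-aestivation the exchanged median was -0.47 for digestive enzymes (turned), -1.53 for fatty acid and sterol synthesis, -0.040 for ribosomal proteins, -0.66 for antioxidant genes, 0.82 for innate immunity and -0.035 for insulin, TOR and AMPK signalling. In arousal over deep aestivation it was -0.64 for fatty acid and sterol synthesis and -0.70 for digestive enzymes (both turned), 0.89 for fatty acid oxidation, 0.96 for ribosomal proteins, 0.76 for translation factors, 0.24 for antioxidant genes, -0.25 for innate immunity and -0.85 for insulin, TOR and AMPK signalling. In arousal over non-aestivation it turned to -2.82 for fatty acid and sterol synthesis, -0.99 for digestive enzymes, 0.87 for ribosomal proteins, 0.57 for translation factors, 0.69 for innate immunity, 0.24 for extracellular matrix and -1.17 for insulin, TOR and AMPK signalling. It was -0.25 for heat shock proteins, -0.59 for the citrate cycle, 0.10 for oxidative phosphorylation, -0.84 for fatty acid oxidation, -0.43 for antioxidant genes and -0.22 for ubiquitin, proteasome and autophagy. Of the values of named isotigs under other pseudocounts and scalings, 821 stayed within their interval and 4 moved.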

Other observations

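The families and isotigs of the first 2 paragraphs, other than isotig13139, were chosen only after their values were seen, as were the tests on family sums, on the median of all isotigs, on the main cell type, on another piece of gut and on exchanged labels. Reads are given for non-aestivation, deep aestivation and arousal in that order. Summed over 19 isotigs, subtilisin/kexin type 9 matches had 107, 1504 and 337 reads, which is 16.1-fold higher in deep aestivation than in non-aestivation (95% counting interval 13.2 to 19.8), and 14 of the 19 isotigs were higher than in both other libraries. Pancreatic-type lipases had 10, 736 and 14 reads over 4 isotigs (84.3-fold, 45.6 to 177) and amylases 13, 172 and 19 over 4 (15.2-fold, 8.63 to 29.0). Apolipoprotein B, the backbone of lipid-carrying particles, had 1773, 13091 and 8906 reads (isotig13070, 8.46-fold, 8.05 to 8.89). Porins, channel proteins of the outer mitochondrial membrane in animals, went the opposite way with 1545, 432 and 11598 reads over 5 isotigs, 3.12-fold lower in deep aestivation than in non-aestivation (2.81 to 3.48) and 25.4-fold higher in arousal than in deep aestivation (23.0 to 28.0). The 70 kDa heat shock proteins had 1216, 965 and 1454 reads over 10 isotigs, of which 0 were at least 2-fold apart beyond counting error. Their sum was 1.10-fold lower in deep aestivation than in non-aestivation (1.01 to 1.20) and 1.42-fold higher in arousal than in deep aestivation (1.31 to 1.55). The other families summed were trypsin-like proteases (1281, 1616 and 259 reads over 4 isotigs, which go both ways), major yolk proteins (25696, 92536 and 102765 over 3), intestinal fatty acid binding protein (16577, 2850 and 51381 over 2), cellular retinol-binding protein (938, 172 and 597 over 6), angiotensin-converting enzymes (305, 248 and 1173 over 6), beta-tubulins (2935, 1056 and 1921 over 5) and 90 kDa heat shock proteins (908, 1033 and 1003 over 2).

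Single isotigs that match enzymes of methyl group and serine metabolism, picked as stated above and without a list or count of the other members, went in different directions. Betaine-homocysteine S-methyltransferase, which remakes methionine with a methyl group from betaine, had 557, 2594 and 36 reads (isotig13345), 5.33-fold higher in deep aestivation than in non-aestivation (4.86 to 5.86) and 76.3-fold lower in arousal than in deep aestivation (54.9 to 109). Dimethylglycine dehydrogenase, which handles the product of that reaction, had 29, 237 and 44 reads (isotig08989), and glycine N-methyltransferase, which uses up methyl groups, had 60, 218 and 11 (isotig19436). Methylenetetrahydrofolate reductase, on the folate route to methionine, had 312, 24 and 918 reads (isotig13139). A phosphoglycerate dehydrogenase isotig had 77, 18 and 278 reads (isotig13269), and a phosphoserine phosphatase isotig 120, 11 and 339 (isotig16443).

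Digestive enzymes higher in a dormant gut than in both other libraries, 9 isotigs with a median smaller log2 ratio of 4.50, are a pattern to follow up. Reads moving between the isotigs of a family are argued against for lipases and amylases. Reads summed over each family were at least 9.58-fold above either library (5.95 to 16.3). Reads without a unique alignment, or aligned to isotigs without a protein match, were not in these sums, so their movement stays open. Scaling, which moves all isotigs of a library alike, is argued against too. The median log2 ratio over all 18352 isotigs was at most 0.16 (0.13 to 0.20). Movement of reads between isotigs stays open for trypsin-like proteases, whose summed reads were 1.44-fold above non-aestivation (1.34 to 1.56) while summed RPKM gave a log2 ratio of 2.00. The same holds for aminopeptidase N (2.21-fold above arousal, 1.74 to 2.80). That best match is also named alanyl aminopeptidase. The membrane alanine aminopeptidase isotig given above was lower than in both other libraries and was not in this sum, so isotigs of this enzyme went both ways. The tests set beforehand decide little: other scalings were tried on isotigs picked for the pattern, and RPKM sums kept 7 of 7 best matches 2-fold higher, but 4 of them, zinc carboxypeptidase and phospholipase A2 included, have 1 isotig each and nothing to sum. A different piece of gut, different food remains or a few unusual animals cannot be told apart from a change of digestive secretion with dormancy, because each stage has 1 library.

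The medians of the energy lists (citrate cycle, oxidative phosphorylation, glycolysis and fatty acid oxidation, 106 isotigs together) were lower in deep aestivation than in both other libraries, pooled at -0.79 over non-aestivation and 1.03 in arousal over deep aestivation. Few single isotigs were lower than in both beyond counting error: 5 of 23 in the citrate cycle, 5 of 62 in oxidative phosphorylation, 0 of 11 in glycolysis and 0 of 10 in fatty acid oxidation. In the last 2 lists the interval of the median over non-aestivation spans 0, and in glycolysis so does that in arousal over deep aestivation. With members at 0 reads set to their bound, medians over non-aestivation and in arousal over deep aestivation lay nearer 0. They were -0.58 and 1.10 in the citrate cycle, -0.76 and 0.69 in oxidative phosphorylation, -0.52 and 0.96 in glycolysis, and -0.88 and 1.34 in fatty acid oxidation. Isotig length is argued against, since among random lists matched on length and mean RPKM the percentile was 0 in the first comparison and 100 in the second. Scaling or a few abundant isotigs are argued against too, since the median of the larger log2 ratio of deep aestivation was at most -0.61 over the 3 other scalings (95% interval -0.79 to -0.37). A lower share of the main cell type of the gut cannot be told apart from a change within cells. Neuronal genes moved the opposite way to the energy lists by their median (0.72, 0.08 to 1.10, and -0.97 in arousal over deep aestivation). Muscle genes, at 0.41 (-0.32 to 1.24), lay 0.31 below the neuronal genes with overlapping intervals. Their median was 0.00 with members at 0 reads set to their bound. In arousal over deep aestivation it was -0.43 (-0.99 to -0.21), or -0.31 at that bound. Calls of single muscle genes went against these medians, with 2 of 31 higher and 4 lower, and then 3 higher and 1 lower. Muscle genes therefore had no clear direction.

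The crossed file names of the outer stages could not be settled from the values. Deep aestivation differed from non-aestivation in 1697 isotigs beyond counting error and from arousal in 1594, a difference of 103, and arousal differed from non-aestivation in 1660. No stage is named inside the tables, so right labels and exchanged labels cannot be told apart. Results on arousal against non-aestivation stay open in direction for this reason.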
